A study of Mus musculus with 714 samples.

How the data were processed

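Single cells from the uterus of ICR mice, sorted for the epithelial surface protein CD326 (EpCAM), had been prepared as CEL-seq libraries, per the labels' protocols. CEL-seq copies the RNA of each cell by in vitro transcription and reads the 3' end of each transcript. The cells came from 5 ages, postnatal day (pnd) 0, 7, 14, 28 and 56. The series text gives 960 sorted cells, and data from 714 were deposited. The rule that removed the others is not given in the sources used here.

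The deposited values are whole-number counts per gene and cell in 1 table of 12479 gene rows and 714 cells, and each cell is a GEO sample of its own. TopHat and Cuffnorm and the mouse genome build mm9 are named in the submitters' processing notes, without roles or versions. The values were taken as raw counts because they are whole numbers from 0 upward with a different total in each cell. Whether molecular identifiers were collapsed is not given in the sources used here, so every interval and floor below covers counting error only. Of all values, 92.3% were 0, and the highest value was 3068. The highest correlation of log counts between any pair of cells was 0.585, so no cell appeared more than once.

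The table has no row for a ribosomal protein gene, a mitochondrially encoded gene, a spike-in or a gene named with the suffix Rik. It also has none for Foxa2, Mki67 or Igf2, so nothing is stated about these genes. Of the rows, 12107 matched a gene name in GENCODE M21, and 11616 of the 21924 protein-coding genes of that annotation have a row. The annotation belongs to another genome build than the authors' and was used for names and neighbouring genes only. Names that a spreadsheet had turned into dates occupied 21 rows, and 1 name was used by 2 rows.

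No label names an animal, a litter or a pool. Each age was therefore treated as 1 sample made of many cells, and no test, p-value or count of changed genes was made from cells. The level of a gene at an age is its sum over the cells, divided by the sum of all genes, in counts per 1000000 (CPM), with an exact Poisson interval. Ratios of a pair of ages carry exact conditional binomial intervals, and shares of cells carry exact Clopper-Pearson intervals, all at 95%. Where one age had 0 counts, a floor of 3 counts over that age gave a bound. Such a bound, given below as "at least", takes the count of the other age without its counting error. The exact conditional interval reaches nearer to no difference than this floor. Where both ages had 3 counts or fewer, no ratio was given. The 5 comparisons were pnd7 with pnd0, pnd14 with pnd7, pnd28 with pnd14, pnd56 with pnd28, and pnd56 with pnd0.

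The cell titles are numbered, and blocks of 96 consecutive numbers form 10 runs, each with cells of 1 age: runs 1 and 2 at pnd0, runs 5, 6 and 10 at pnd7, runs 3, 4 and 7 at pnd14, run 9 at pnd28 and run 8 at pnd56. The labels do not say what these blocks are. They served as a technical split, and since no run holds 2 ages, age and run cannot be told apart.

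Before the data were examined, a rule was written for the genes to be named. A gene needed at least 50 counts over both ages and a count in at least 10% of the cells of the higher age. Every run of one age also had to lie above every run of the other. Genes were ranked by the bound of the 95% interval nearest to no difference, and the first 12 in each direction were taken. This gave 120 results on 95 genes. Members of the fixed gene lists could be named with their values as well. Genes named outside this rule were chosen after their values were seen. These are Hbq1b, Astx4b and Upk3a (with the counts of Adh1 and H19 in the cluster that Upk3a leads), together with Stab1, Skiv2l and Cfb, which are named only as neighbours of other genes.

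The 29 gene lists, also fixed beforehand, were epithelial keratins and junctions, Mullerian and uterine patterning factors, Wnt pathway and targets, epithelial progenitor candidates, retinoid metabolism and targets, steroid receptors and cofactors, oestrogen-responsive uterine genes, progesterone-responsive uterine genes, secretory and antimicrobial proteins, MHC and interferon, imprinted fetal growth genes, fetal and early postnatal RNA-binding and chromatin genes, S phase, G2 and M phase, immediate early and heat shock genes, oxidative phosphorylation, glycolysis and hypoxia, cholesterol and lipid synthesis, Notch, Hedgehog, FGF and BMP signalling, and the markers of luminal epithelium, glandular epithelium, ciliated epithelium, squamous and basal epithelium, stroma and fibroblasts, smooth muscle, endothelium, immune cells, erythroid cells and mesothelium. Lists can share members. The oestrogen and secretory lists share Ltf, Lcn2, Clu, Muc1, Muc4 and Agr2, so their medians are not independent. Lists of ribosomal protein and mitochondrially encoded genes had been planned and could not be measured. A list member counted as measured with at least 20 counts over both ages, and a list needed at least 5 such members for a median. Each median log2 ratio has an interval from 1000 Poisson draws of the counts. It also has a percentile among 10000 random lists of the same size, matched on mean level in 20 bins, as a description of these libraries. Members at least 2-fold higher and at least 2-fold lower were counted as a rule of size.

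Shares of cells with a count of a gene were computed for 27 genes fixed beforehand, of which 3 have no row. To compare ages of different depth, each cell was thinned to 1500 counts, the 20th percentile of the cell totals rounded down. Thinning left out 9, 13, 60, 23 and 20 cells of pnd0, pnd7, pnd14, pnd28 and pnd56.

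Cells with at least 500 counts and 200 genes were clustered, which left out none of the 714. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, 20 principal components, 15 neighbours and Leiden resolution 1.0 with seed 0 gave 10 clusters. A cluster was called after a cell type only where at least 3 of the type's fixed markers, each with at least 10 counts, were at least 3-fold above the other cells, after 20 CPM was added to both sides. A further condition, that leading genes be present in at least 25% of the cluster's cells, was set after a first pass in which single cells had decided names. It left cluster 2 (30.1% of pnd0, 15.7% of pnd7 and 8.67% of pnd14 cells), cluster 6 (53.8% of pnd14 cells) and cluster 8 (89.3% of pnd28 and 17.8% of pnd56 cells) without a name. Clusters 0, 1, 3, 4 and 5 had none with or without it. No doublet caller was run, since cells were sorted singly into wells.

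Genes whose counts over cells had a correlation of at least 0.9 and were equal in at least 80% of cells with a count were read as sharing reads. Among 4867 genes searched this gave 83 pairs in 47 groups with 104 genes. The extra members of these groups held 2.80% of all counts. The Hba-a1 and Hba-a2 pair, the Sprr2a2 and Sprr2a3 pair and the Ugt1a family were among them. Each such group is read as 1 signal where its genes are named. The clustering and the main list values kept every row of a group. No clustering with such rows merged was run.

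The procedures were tested on simulated data in which each cell was drawn from the pooled profile of the earlier age and 200 genes were changed. The intervals held the true ratio for 96.3% of genes in the pnd7 and pnd0 comparison, with 96.0%, 96.4%, 96.4% and 97.3% in the others. Of genes changed 4-fold, the naming conditions other than the share of cells and the rank recovered 100% in each adjacent comparison and 90.5% in the pnd56 and pnd0 comparison. Of genes changed 2-fold they recovered 89.4% (76 of 85), 80.3% (57 of 71), 69.8% (44 of 63), 88.6% (62 of 70) and 66.2% (43 of 65), in the order of the comparisons above. All simulated genes with at least 50 counts, changed or not, numbered 4164, 3661, 1938, 654 and 2743. Unchanged genes met the same conditions in 3.45%, 3.16%, 4.17%, 5.13% and 3.19% of cases. The simulation holds no variation between animals and none between cells beyond counting.

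Alternatives fixed beforehand were equal weight for every cell, cells with at least 1000 counts, thinned cells, median-of-ratios size factors over 184 genes, a total without the 20 most abundant genes, leaving out the 28 smooth muscle-like cells, leaving out each of 8 runs in turn, list minimums of 1 and 100 counts, cell shares at 2 counts, and other clustering settings. A further 3 were chosen after seeing the data: genes that share reads kept as 1 row, each gene without the cell that holds its largest count, and all genes without the pnd28 cell with the most Prss29. A list's value was read as having a direction only where its interval left out 0 and its percentile was at most 2.5 or at least 97.5. The percentile part of this rule, the absence of a ratio where both ages had 3 counts or fewer, and the choice of the 12 results treated as the answers to the comparisons were also set after seeing the data.

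Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, igraph 0.11.9 and matplotlib 3.10.9.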

Results

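The series followed the epithelium of the mouse uterus from birth to adulthood, one cell at a time, to order its cell states along development. The table holds 173 cells of pnd0, 267 of pnd7, 173 of pnd14, 56 of pnd28 and 45 of pnd56. Each age stands as 1 sample, with no replicate check on any difference between ages, and the intervals given are 95% intervals of counting error only. The ages sum to 582615, 732957, 354047, 96248 and 81894 counts. Depth per cell was lower at the later ages, with medians of 3037, 2492, 1782, 1600 and 1670 counts and 1125, 975, 702, 648 and 689 genes detected. At an equal depth of 1500 counts the median number of genes was 775, 749, 671, 657 and 673. The median log2 ratio of all genes with at least 20 counts was −0.03 for pnd7 over pnd0, −0.10 for pnd14 over pnd7, −0.23 for pnd28 over pnd14, 0.06 for pnd56 over pnd28 and −0.34 for pnd56 over pnd0. Ratios below are read against these values. Median-of-ratios scaling moves the last pair by −0.13 and −0.27, and thinning moves pnd56 over pnd0 by 0.32.

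Epithelial keratin marked most cells of the sort at each age, and a small group of cells carried muscle genes. Krt18, a keratin of simple epithelia, was present in 98.8% of pnd0, 98.9% of pnd7, 91.9% of pnd14, 78.6% of pnd28 and 91.1% of pnd56 cells. Epcam, the gene of the sorted protein, was present in 50.9%, 44.2%, 34.1%, 28.6% and 53.3%. Krt8, the usual partner of Krt18, had counts in 3 cells in all, 1 each at pnd0, pnd14 and pnd28, so its row carries no information. Among 10 clusters, 28 cells were smooth muscle-like by Myl9, Des, Cnn1 and Mylk. They were 13.3% [8.62, 19.3] of pnd14 cells and 8.93% [2.96, 19.6] of pnd28 cells, and the pnd14 share was 11.4%, 8.33% and 16.5% in runs 3, 4 and 7. In these pnd14 cells, with a median of 1640 counts, Epcam was present in 8.70% and Krt18 in 52.2%, against 38.0% and 98.0% of the other pnd14 cells, with a median of 1794 counts. A cluster of 35 cells, all of pnd56 and 77.8% of that age, was luminal epithelium-like by Sprr2f, Prap1 and Fxyd3. Of the 10 clusters, 5 took at least 80% of their cells from 1 age, and with 1 sample per age such a cluster may be that library and not a cell type.

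Markers of blood were highest at birth, with nearly all Hba-a1 counts of that age in 1 run. Markers of stroma were highest at the latest ages, with many of the counts in few cells. Stroma and fibroblast markers held 0.00978%, 0.0157%, 0.0915%, 0.341% and 0.339% of counts over the 5 ages. At pnd28 the smooth muscle-like cells held 161 of the 328 stroma counts. At pnd56 single cells held 54 of the 63 Col3a1 and 24 of the 29 Dcn counts. The erythroid list held 1.35% of pnd0 counts against 0.0327%, 0.0268%, 0.0218% and 0.00244% at pnd7, pnd14, pnd28 and pnd56. These shares hold Hba-a1 and Hba-a2 as separate rows, with 3919 and 3893 counts at pnd0, although they share reads. A pair of pnd0 cells in run 1 held 3068 and 762 of the 3918 Hba-a1 counts of that run, and 34 of its 88 cells had a count against 1 of 85 cells in run 2. In run 2 Hba-a1 stood at 3.48 CPM, below the 152, 204.5 and 120 CPM of the pnd7 runs 5, 6 and 10. Hbq1b, a haemoglobin theta gene, had 905 counts in that pair of cells and none in the others of run 1. The smooth muscle list held 0.00704%, 0.0183%, 0.283%, 0.130% and 0.0110% of counts over the 5 ages. Immune markers held 0.00687%, 0.0112%, 0.00960%, 0.0665% and 0.0330%, and Ptprc, the common leukocyte gene, was counted in 1 pnd0 cell. Mesothelial markers held 0.0179%, 0.00846%, 0.0336%, 0.0281% and 0.00733%, led at pnd14 by 82 counts of Wt1. Squamous and basal markers held 0.00841%, 0.00710%, 0.00452%, 0.0478% and 0.0256%, led at pnd28 by 17 counts of Trp63, the basal cell regulator. Ciliated markers held 0.00258%, 0.00164%, 0.0240%, 0.00416% and 0.00122%, with 85 counts at pnd14, 39 of them of Ccno.

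**Figure D1:**
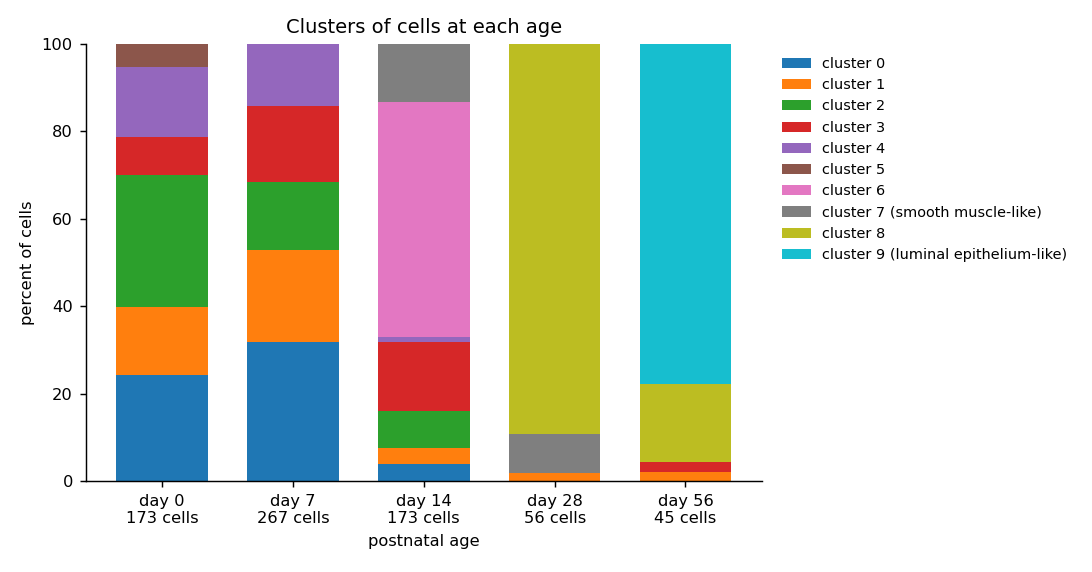
Percent of the cells of each age (stacked bars, y axis in percent) that fell in each of the 10 clusters. The bars of pnd0 and pnd7 share their clusters except 1, which holds 5.20% of pnd0 and no pnd7 cells, while 53.8% of pnd14, 89.3% of pnd28 and 77.8% of pnd56 cells lie in a cluster that leads at that age.

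The first comparison asks how the epithelium of the first week differs from that at birth, before glands form. Aldh1a1, whose enzyme makes retinoic acid, stood at 172 CPM at pnd7 against 22.3 at pnd0, 7.70-fold higher, with a log2 ratio of 2.95 [2.12, 3.89]. It was counted in 23.6% of pnd7 cells against 5.20% of pnd0 cells, and in 15.7% against 3.05% at equal depth. Esr1, the gene of oestrogen receptor alpha, was at 92.8 CPM against 17.2, a log2 ratio of 2.43 [1.47, 3.56] that stood at 3.15 without run 1. Slc5a11, a sodium-coupled inositol transporter, was at 109 CPM, 9.08-fold higher, Car2, a carbonic anhydrase, at 225 against 51.5, and Plat, the tissue plasminogen activator, at 754.5 against 232. Scnn1a, a subunit of the epithelial sodium channel, was at 95.5 CPM against 534 at birth, a log2 ratio of −2.48 [−2.88, −2.10]. The imprinted long non-coding RNA Meg3 was at 87.3 against 378 CPM, and Fads1, a fatty acid desaturase, at 69.6 against 240. Adh1, an alcohol dehydrogenase that oxidises retinol, was at 13.6 against 204 CPM, and its log2 ratio of −3.90 was −4.55 without run 1 and −2.74 without run 2. Of its 119 pnd0 counts, 102 lay in a cluster of 9 pnd0 cells led by Upk3a, and the other pnd0 cells stood at 30.2 CPM [17.6, 48.3], so most of the difference belongs to these 9 cells. The 12 named higher genes ran from log2 1.59 for Tgfbi to 3.18 for Slc5a11. The 12 lower ones ran from −1.79 for Fads1 to −4.31 for Rasa4, which stood at −3.48 without run 2.

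Among gene lists, genes that respond to oestrogen lay higher at pnd7 and retinoid genes lay lower. The median log2 ratio of the oestrogen-responsive genes was 0.57 [0.29, 1.15] at percentile 99.9, with 5 of 13 members at least 2-fold higher and none lower, and 0.27 without run 1. Sprr2b, a cornified envelope protein gene induced by oestrogen, had 2.05, while Clu, a secreted chaperone, had −0.37. The luminal epithelium markers had 0.46 [0.29, 0.85] at percentile 99.8, led by Lpar3, a lysophosphatidic acid receptor, at 2.99. The retinoid list had −0.39 [−0.60, −0.15] at percentile 0.2 although Aldh1a1 belongs to it, with Fabp5, a fatty acid and retinoic acid carrier, at −1.59. The MHC and interferon list had 0.28 [0.09, 0.53] at percentile 98.5, with Psmb8, an immunoproteasome subunit, at 1.60. The other 16 lists with a median lay between percentiles 3.16 for imprinted genes and 95.8 for progenitor candidates. Among these, keratins and junctions had −0.14, patterning factors 0.13, Wnt genes −0.02, progenitor candidates 0.28, steroid receptors 0.15, progesterone-responsive genes 0.29 and secretory proteins −0.25. Imprinted genes had −0.38, fetal chromatin genes 0.17, S phase 0.12, G2 and M phase 0.19, immediate early genes 0.02, oxidative phosphorylation 0.07, glycolysis −0.06, cholesterol synthesis 0.14 and Notch, Hedgehog, FGF and BMP signalling −0.18.

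**Figure D2:**
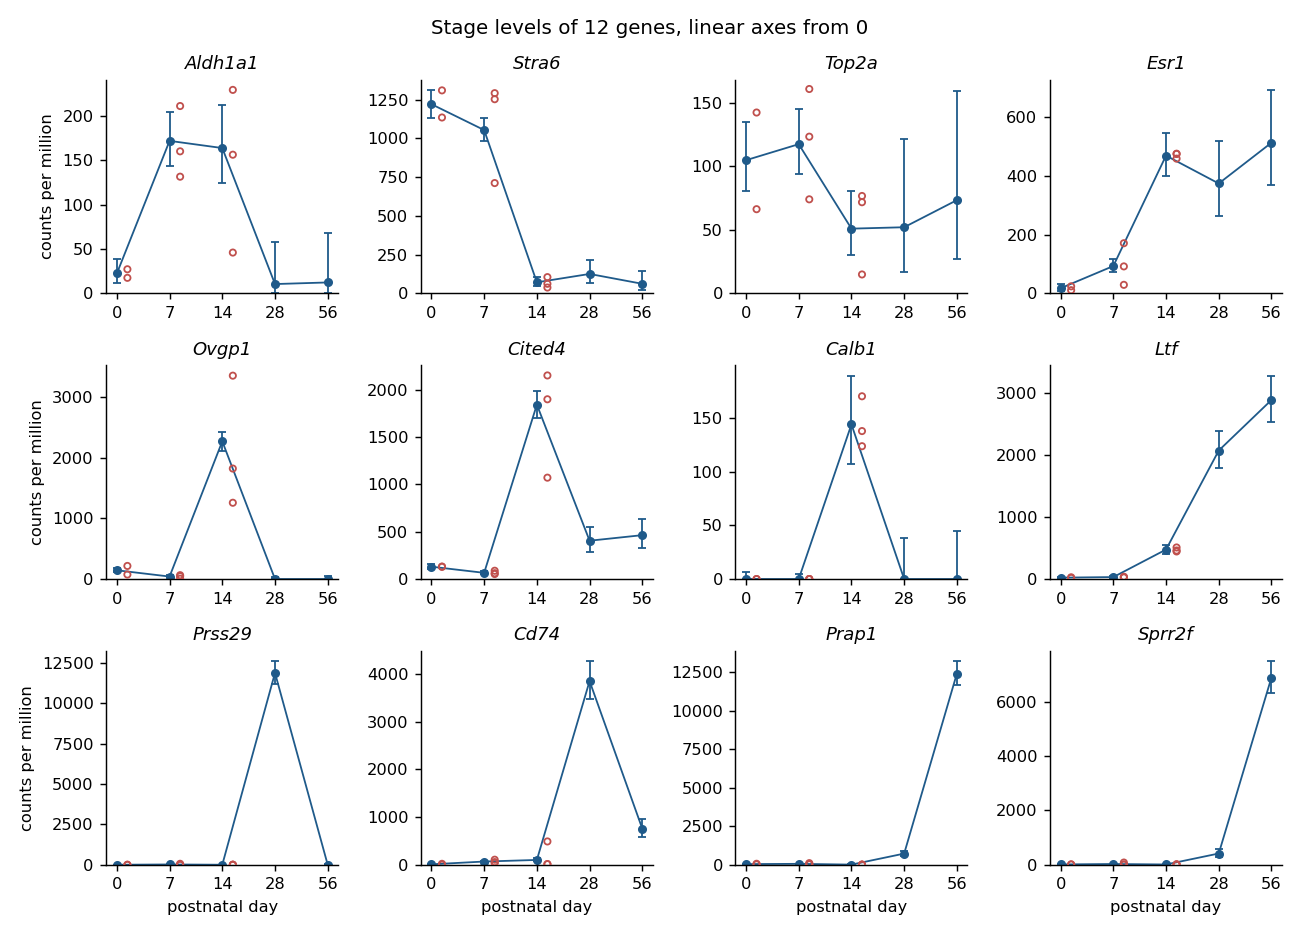
Level in CPM (y axes, linear from 0) of 12 genes at the 5 ages (x axes); filled points with bars are the age with its 95% Poisson interval and open circles are the runs of pnd0, pnd7 and pnd14. Aldh1a1 stands at 172 CPM at pnd7 and Ovgp1 at 2271 CPM at pnd14, while Prap1 reaches 12420 CPM at pnd56.

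The comparison of pnd14 with pnd7 covers the time in which uterine glands begin to bud. Ovgp1, the gene of the oviduct-specific glycoprotein, stood at 2271 CPM at pnd14 against 40.9 at pnd7, 55.5-fold higher, with a log2 ratio of 5.79 [5.27, 6.37] that was 5.14 without run 7 and 6.41 without run 10. It was counted in 33.5% of pnd14 cells, and 717 of its 804 pnd14 counts lay in 42 cells of 2 clusters. Cited4, a transcriptional co-activator, was at 1844 against 65.5 CPM, a log2 ratio of 4.82 [4.39, 5.27]. Acot7, an acyl-CoA thioesterase, was at 2251 against 113 CPM, and Cbr2, a carbonyl reductase, at 1474 against 68.2. The junction genes Jam2 and Cldn10 were at 545 against 20.5 and 212 against 8.19 CPM, with log2 ratios of 4.74 and 4.69 that stood at 5.36 and 5.80 without run 6. Calb1, a calcium-binding protein of the luminal epithelium, had 144 CPM at pnd14 and no count at pnd7, at least 35.2-fold higher, with a bound of 5.14 on the log2 scale and 4.43 without run 10. The muscle genes Cnn1, Des and Myl9 were among the named ones. They also gave the smooth muscle-like cells their name, so lower ratios without these cells follow from that choice. Without these cells the log2 ratio of Cnn1 moved from 5.40 to 3.09, that of Des from 4.43 to 1.72 and that of Myl9 from 3.75 to 2.08. Each thus stayed higher at pnd14 in the remaining cells. Without run 10 Cnn1 stood at 4.69, and Des stood at 5.17 without run 5 and 3.80 without run 7. The 12 higher genes ran up to 5.86 [3.94, 8.94] for Cyp2f2, which had 2 counts at pnd7.

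Stra6 and Crabp1 were among the named lower genes at pnd14, and both cell division lists lay lower. Stra6, the membrane receptor that takes up retinol, stood at 70.6 CPM against 1053 at pnd7, a log2 ratio of −3.90 [−4.54, −3.33] and −4.55 without run 7. Crabp1, a retinoic acid-binding protein, was at 11.3 against 341 CPM with −4.92 [−6.80, −3.54], and −4.10 without run 7. The TEAD transcription factor Tead2 was at 189 against 911 CPM. Ece2, a peptide-processing enzyme, had no count at pnd14 and 112 CPM at pnd7, at least 13.2-fold lower, with a bound of −3.72 on the log2 scale, −3.03 without run 3 and −2.90 without run 7. Igfbp2, an insulin-like growth factor-binding protein, had the lowest named ratio, −5.80 from 1 count at pnd14, which stood at −5.10 without run 3. Without run 7, which holds that count, only a bound of −3.39 is left. Nt5dc2, at −2.96, lies within 2 kb of Stab1, so its counts may hold reads of that neighbour. The median of the G2 and M phase list was −1.44 [−1.84, −1.08], at percentile 0, with 13 of 17 members at least 2-fold lower, and −1.03 without run 3. The mitotic kinase Aurkb had −3.24 and the survivin gene Birc5 −1.86. The S phase list had −1.01 [−1.43, −0.80] at percentile 0.01, with 12 of 24 members lower, among them the replication helicase gene Mcm5 at −1.88. Imprinted genes had −1.05 [−1.68, −0.62] at percentile 0.26, −1.95 without the smooth muscle-like cells and −1.65 at equal depth, with the growth regulator Grb10 at −4.00, and fetal chromatin genes −0.61 at percentile 1.42.

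Progesterone-responsive genes showed the highest list median of this comparison among epithelial functions. It was 2.59 [2.05, 2.98] at percentile 100, with 6 of 8 members at least 2-fold higher. Beside Calb1 these included the endocytic receptor Lrp2 at 4.57, the kinase Sgk1 at 3.41 and the transcription factor Gata2 at 1.76. Stroma markers had 2.69 [2.24, 3.28] and endothelium markers 1.43 [0.95, 2.22], and without the smooth muscle-like cells these were 1.05 and 0.79. The stroma value was 3.76 without run 10. The MHC and interferon list had 0.44 [0.03, 0.59] at percentile 99.0, with the sign lost at equal depth (−0.01) and at a minimum of 100 counts (−0.22). The secretory list had 0.63 [−0.37, 1.29], an interval that includes no difference, with the whey acidic protein-type Wfdc18 at 3.21. The oestrogen list split, with 6 members higher and 7 lower and a median of −0.55 that was 0.06 without run 7. In it Ltf, the lactoferrin gene, had 3.92 and the water channel Aqp5 −3.10. Of the pnd14 counts, 116 of 168 of Ltf and 101 of 139 of Wfdc18 lay in 42 cells of the pair of clusters with the most Ovgp1. Cholesterol synthesis had −0.51 at percentile 2.36. With the oestrogen list, 12 lists lay between percentiles 2.68 for glycolysis and 87.3 for immediate early genes. The luminal list had −0.38, and 0.34 without run 6, the Wnt list −0.59 and the retinoid list −0.49.

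The comparison of pnd28 with pnd14 comes next, and the age labels give no pubertal status. A pair of serine protease genes of uterine glands set pnd28 apart. Prss29 stood at 11890 CPM against 1 count at pnd14, a log2 ratio of 12.04 [9.56, 17.34] that was 11.22 without run 7. Without run 3, which holds that count, pnd14 has none and only a lower bound of 9.76 is left. Prss28 stood at 5787 CPM against no count, at least 683-fold higher, with a bound of 9.42 on the log2 scale, 8.72 without run 3 and 8.60 without run 7. A single cell held 670 of the 1144 Prss29 counts and 388 of the 557 Prss28 counts, and without it the bound of Prss28 was 7.75 and the log2 ratio of Prss29 10.82. Prss29 was counted in 92.9% of pnd28 cells, and its level in the 5 smooth muscle-like cells, 4074 CPM, was close to the 5221 CPM of the other cells without the largest. This share is therefore not read as the share of cells that express the gene. With these genes, the glandular list took 1.86% of pnd28 counts, against 0.0110%, 0.0274% and 0.0322% at pnd0, pnd7 and pnd14 and 0.252% at pnd56, where 191 of its 206 counts were of Spink12. Spink12, a protease inhibitor gene, was at 800 CPM against 5.65 at pnd14, and its log2 ratio of 7.15 was 6.45 without run 3 and 5.86 without the cell of its largest count. Without run 7, which holds its pnd14 counts, only a lower bound of 5.74 is left.

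Antigen presentation and oestrogen-responsive genes lay higher at pnd28. Cd74, the invariant chain of MHC class II, stood at 3855 CPM against 102 and was counted in 67.9% of pnd28 cells. Its log2 ratio of 5.24 [4.75, 5.78] was 4.63, 8.12 and 4.51 without runs 3, 4 and 7, since 1 cell of run 4 held 24 of the 36 pnd14 counts. The class II chain H2-Ab1 was at 603 against 16.9 CPM, and H2-Eb1 had 46 counts against none, at least 56.4-fold higher. The MHC and interferon list had a median of 1.22 [0.88, 1.70] at percentile 100, and 1.71 without run 7, with 10 of 17 members at least 2-fold higher. The interferon-induced Ifitm1 was the only member at least 2-fold lower, at −1.08. Immune cell markers were higher as well, with 64 counts against 34 and a log2 ratio of 2.79 [2.17, 3.44] for their sum. The oestrogen list had 1.93 [1.66, 2.17] at percentile 100, with 9 of 12 members higher, among them Ltf at 2.12, Clu at 2.10, Car2 at 1.90 and Sprr2f at 5.20. The secretory list had 2.10 [1.48, 2.22], with Pigr, the receptor that carries immunoglobulins across epithelia, at least 45.4-fold higher, where 1 cell held 18 of its 37 counts. Prap1, a proline-rich secreted protein gene, was at 727 against 11.3 CPM.

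Several genes of the pnd14 cells were missing or low at pnd28. Ovgp1 had no count in 56 cells, against 2271 CPM, at least 72.9-fold lower, with a bound of −6.19 on the log2 scale and −5.53 without run 7. Of its 804 pnd14 counts, 717 lay in 42 cells of 2 clusters. A loss of expression and a difference in the cells sampled cannot be told apart here. A count of 0 in 56 cells allows up to 5.36% of pnd28 cells with a count by 3 counts of the total and 6.38% by the exact interval, which does not limit the share that expresses the gene. Acot7 was at 145.5 against 2251 CPM, Jam2 at 20.8 against 545, and Galm, a sugar mutarotase, at 52.0 against 780. The long non-coding RNA Rmst and the growth factor receptor Fgfr2 had no count, at least 13.1-fold and 8.34-fold lower, with bounds of −3.71 and −3.06 that were −3.01 and −2.00 at equal depth. The 12 lower genes ran from −2.47 for Phax to the bound of Ovgp1, and the 12 higher ones from 4.75 for Fabp5, which stood at 4.06 without run 3 and 7.33 without the cell of its largest count, to Prss29. The progesterone list had −1.29 [−1.69, −0.83] at percentile 0.22, with Gata2 at −3.01, the itaconate-making enzyme Irg1 at −3.51 and Sgk1 the other way at 1.81. That median was −0.07 at equal depth and 0.0046 with a minimum of 1 count, so its direction rests on the settings. The steroid receptor list had 1.17 [0.25, 1.49] and −0.01 at equal depth, and within it Pgr, the progesterone receptor gene, had −2.44 and Esr1 −0.33. Stroma markers had 1.37 [0.91, 1.79] and −0.01 without the smooth muscle-like cells. The other 15 lists lay between percentiles 7.41 for Wnt genes and 97.7 for S phase. S phase had 0.44 with an interval of −0.12 to 0.79, and endothelium −0.94, which was −0.04 without run 3.

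**Figure D3:**
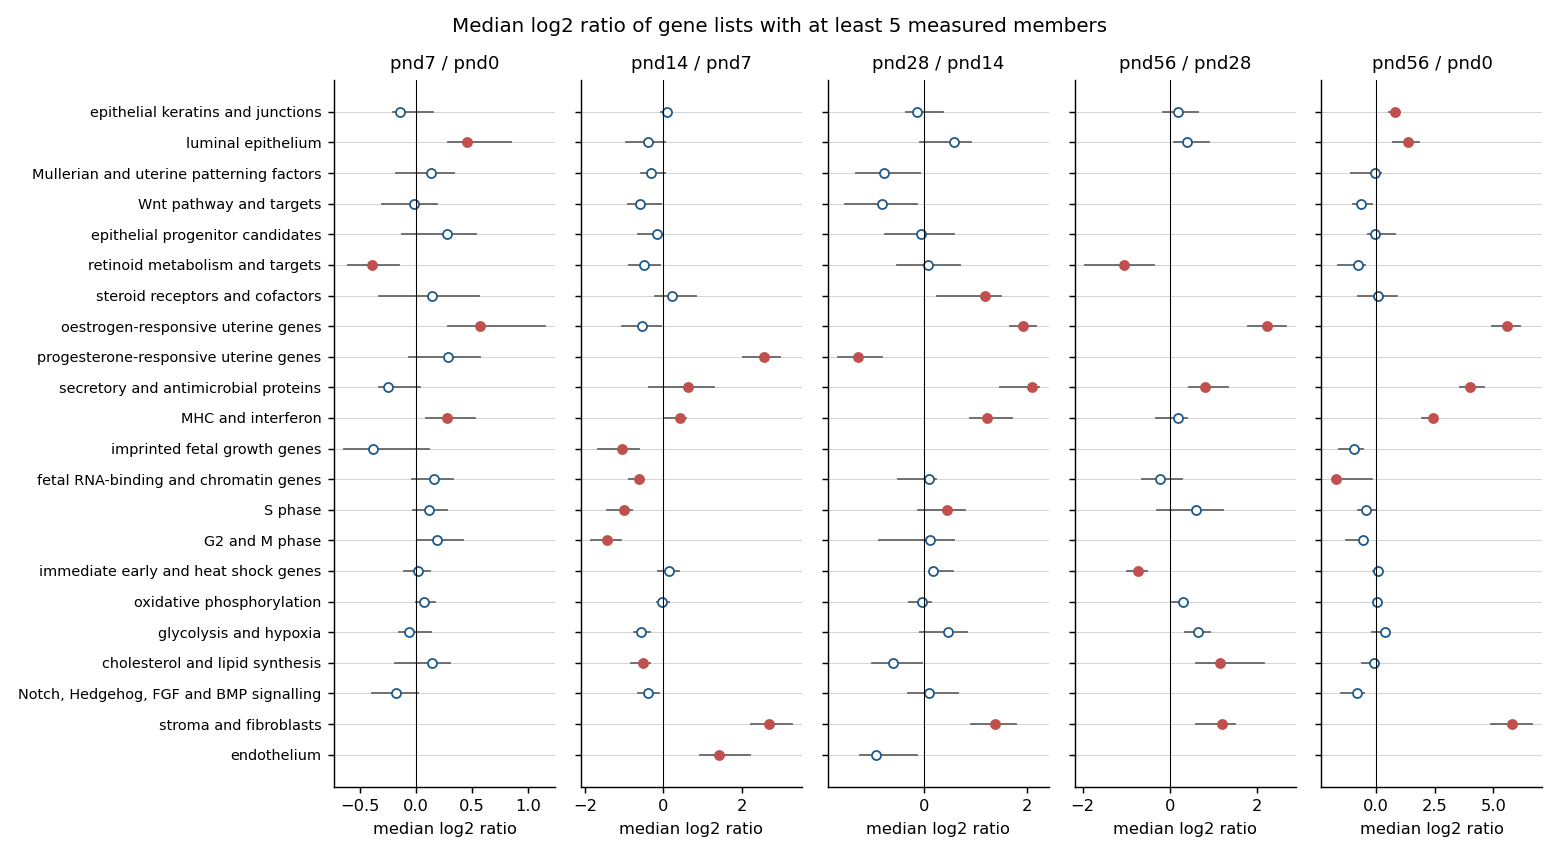
Median log2 ratio (x axis) of each gene list (y axis) in the 5 comparisons (panels), with 95% intervals from Poisson draws; filled red points lie outside the central 95% of matched random lists. The oestrogen list lies at 0.57, 1.93, 2.23 and 5.57 in the panels in which it is red.

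The comparison of pnd56 with pnd28 sets the adult epithelium against that of pnd28. The age labels give neither pubertal status nor stage of the oestrous cycle, so neither can be told apart from age. Small proline-rich proteins and secreted proteins of the oestrogen-exposed uterus stood high in the adult. Sprr2b was at 7278 CPM against 145.5, a log2 ratio of 5.64 [4.89, 6.53], and Sprr2f at 6899 against 416, a log2 ratio of 4.05 [3.59, 4.55]. Sprr2a2 and Sprr2a3, which share reads and count as 1 signal, were at 4872 and 4921 against 561 CPM. Prap1 stood at 12420 against 727 CPM, a log2 ratio of 4.09 [3.74, 4.47]. Spp1, the osteopontin gene, was at 1490 against 20.8 CPM, Padi2, an oestrogen-responsive peptidylarginine deiminase, at 806 against 41.6, and Klk1, a kallikrein, at 782 against 83.1. Nelfe was at 5617 against 1018 CPM, and it lies within 2 kb of Skiv2l and of Cfb, a complement factor gene induced in the uterus by oestrogen, so its counts may not be its own. The oestrogen list had a median of 2.23 [1.79, 2.66] at percentile 100, with 10 of 14 members at least 2-fold higher, among them the mucins Muc4 at 4.14 and Muc1 at 1.80. It took 0.432%, 0.505%, 0.992%, 1.73% and 4.17% of counts over the 5 ages. Shares and member counts of this list hold Sprr2a2 and Sprr2a3 as separate rows, with 399 and 403 counts at pnd56, so that signal enters more than once. The secretory list had 0.82 [0.44, 1.33] and cholesterol synthesis 1.15 [0.61, 2.17], which was 0.49 with equal weight for every cell.

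The protease genes of pnd28 had no count in the adult. Prss29 was at least 324.5-fold lower, with a bound of −8.34 that was −7.12 without the pnd28 cell of its largest count, and Prss28 at least 158-fold lower, with a bound of −7.30 that was −5.63 without the same cell. Slc5a11, at 852 CPM in pnd28, also had no count in 45 cells, at least 23.3-fold lower. Id3, an inhibitor of differentiation, was at 48.8 against 613 CPM and the matrix protein gene Tgfbi at 97.7 against 1153. Cd74 was at 757 against 3855 CPM, a log2 ratio of −2.35 [−2.76, −1.96], and 1 cell held 52 of its 62 pnd56 counts, without which it was at 124 CPM. Mmp2, a matrix metalloprotease of stromal cells, had −3.41, and −1.72 without the smooth muscle-like cells. Immediate early and heat shock genes had −0.74 [−0.98, −0.53] at percentile 0.28, with Fos at −1.09 and Egr1 at −1.05. The retinoid list had −1.06 [−1.96, −0.35] at percentile 2.27 and 0.16 with a minimum of 1 count, with the retinaldehyde reductase Dhrs3 at −2.55. Stroma markers had 1.20 [0.60, 1.49], 3.74 without the smooth muscle-like cells and −1.87 without each gene's largest cell, since 1 cell held 54 of the 63 Col3a1 and 28 of the 39 Vim counts of pnd56. The other 7 lists lay between percentiles 25.6 for fetal chromatin genes and 92.9 for glycolysis, with MHC and interferon genes at 0.18, keratins at 0.19, the luminal list at 0.39 and S phase at 0.61.

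The last comparison spans the whole series, pnd56 over pnd0. Sprr2a3 stood at 4921 against 5.15 CPM, from 3 counts at birth, a log2 ratio of 9.90 [8.34, 12.18] and 10.51 without run 2. Sprr2f was at 6899 against 13.7 CPM with 8.97, and Ltf at 2882 against 22.3 CPM with 7.01 [6.21, 7.94]. Prap1 was at 12420 against 44.6 CPM with 8.12, and 9.03 without run 2, and Cbr2 at 6826 against 32.6 CPM with 7.71, and 8.39 without run 2. Pigr was at 635 CPM against no count, at least 123-fold higher, with a bound of 6.95 that was 5.93 without run 1 and 5.97 without run 2. Spink12 had the highest ratio, 10.41 from 1 count at pnd0, which stood at 9.39 without run 1. Without run 2, which holds that count, only a lower bound of 7.84 is left. H19, the imprinted growth-restraining RNA, had no count in adult cells against 597 CPM, at least 16.3-fold lower, with a bound of −4.03 that was −4.75 without run 1 and −2.59 without run 2. The 9 pnd0 cells of the Upk3a-led cluster held 271 of its 348 counts at birth, and the other pnd0 cells stood at 137 CPM [108, 171]. Meg3 was at least 10.3-fold lower, with a bound of −3.37 that was −2.21 at equal depth, Stra6 at 61.0 against 1220 CPM with −4.32, Id3 at 48.8 against 937 with −4.26, and Ifitm1 at 1441 against 8429 with −2.55. The Hba-a1 and Hba-a2 signal, absent at pnd56, belongs to the pair of pnd0 cells described above, with a bound of −7.52 for Hba-a1 that was −5.34 without the largest cell and −8.50 without run 2.

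The oestrogen list separated the adult from birth more than any other epithelial list with a median. Its value was 5.57 [4.95, 6.10] at percentile 100, with 12 of 15 members at least 2-fold higher, and 4.72 without run 1. The secretory list had 3.98 [3.56, 4.61], and 3.11 with a minimum of 1 count, with 7 of 8 members higher and Wfdc2, an antiprotease abundant at birth, the other way at −1.18. As it shares genes such as Ltf, Clu, Muc1 and Muc4 with the oestrogen list, its median is not a separate result. MHC and interferon genes had 2.43 [1.98, 2.62], and 1.66 with a minimum of 100 counts, with 11 of 16 members higher, 4 lower and H2-D1 at 3.81. The luminal list had 1.37 [0.76, 1.86], 0.75 with genes that share reads as 1 signal and 1.99 with a minimum of 100 counts, and keratins and junctions 0.80 [0.55, 1.05] at percentile 98.3. Stroma markers had 5.77 [4.88, 6.65], 5.11 without run 1 and 3.63 without each gene's largest cell. Fetal chromatin genes had −1.69 [−1.87, −0.15] at percentile 0.075, but −0.87 at equal depth and −0.21 with a minimum of 1 count, with the de novo DNA methyltransferase Dnmt3a at −3.70 and Marcksl1, an actin-regulating protein gene, at −2.85. The other 13 lists lay between percentiles 4.56 for the retinoid list and 90.8 for steroid receptors, with S phase at −0.42 and G2 and M phase at −0.54.

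Shares of cells were set against depth by thinning, and values in brackets are shares at 1500 counts. Ltf was counted in 2.89% (1.22%), 3.0% (2.36%), 16.8% (15.9%), 62.5% (57.6%) and 48.9% (48.0%) of cells over the 5 ages. At pnd28 it was counted in 0 of 5 smooth muscle-like cells and in 68.6% of the others. Esr1 was counted in 3.47% (1.22%), 10.1% (7.87%), 38.7% (37.2%), 39.3% (33.3%) and 48.9% (40.0%). The 47.8% of smooth muscle-like pnd14 cells with Esr1 cannot serve as its background, since uterine muscle expresses the gene too. Wnt7a, a Wnt ligand of the uterine epithelium, was counted in 38.1% (26.8%), 33.7% (26.0%), 7.51% (7.96%), 12.5% (18.2%) and 6.67% (12%), and in 0 of 23 smooth muscle-like pnd14 cells. Top2a, the mitotic topoisomerase gene, was counted in 15.6% (6.71%), 16.9% (12.6%), 6.94% (6.19%), 5.36% (0%) and 4.44% (0%). Calb1 was counted in 17.9% (15.9%) of pnd14 cells and in no cell of another age. Its share was 17.4% [4.95, 38.8] in the smooth muscle-like and 18.0% [12.2, 25.1] in the other pnd14 cells, so which cells express it cannot be read from these shares. Trp63 was counted in 16.1% (15.2%) of pnd28 cells and in no more than 2.31% at any other age. The stem cell candidates Lgr5, Axin2, Sox9 and Prom1 were counted in at most 9.36% of cells of any age, and Axin2, a Wnt target, in none of the pnd28 and pnd56 cells. At 56 and 45 cells a count of 0 allows up to 5.36% and 6.67% of cells with a count by 3 counts of the total, or 6.38% and 7.87% by the exact interval, and sets no limit on cells that express a gene at this depth.

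**Figure D4:**
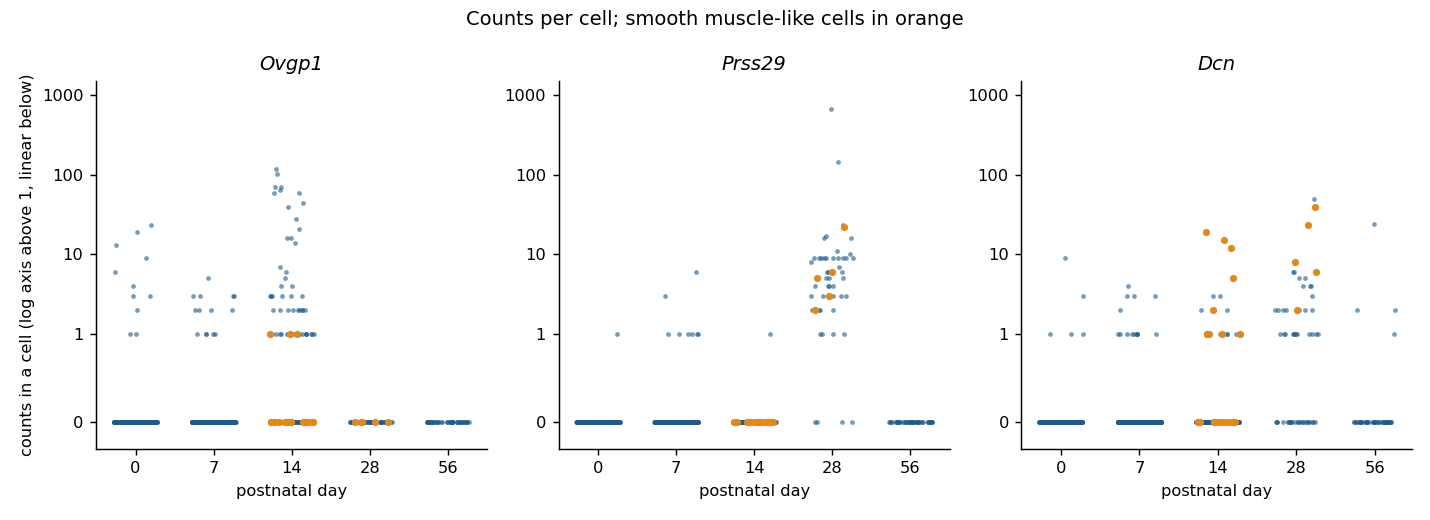
Counts per cell (y axis, logarithmic above 1 and linear below) of Ovgp1, Prss29 and Dcn at the 5 ages (x axis), each point 1 cell and smooth muscle-like cells in orange. Prss29 is counted in 92.9% of pnd28 cells with 670 counts in 1 of them, and Ovgp1 in no pnd28 or pnd56 cell.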

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

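The settings that leave out a gene's largest cell, the pnd28 cell with the most Prss29, or the extra members of groups with shared reads were chosen after the results were seen; the others were fixed before the data were examined. The named genes kept their direction in every setting run, with 1284 of 1385 values inside the interval of counting error of the reported value and 101 outside it. Part of this follows from the naming rule, which required every run of one age to lie above every run of the other. Leaving out a run therefore says little about direction for these genes. Cells thinned to equal depth gave 34 of these 101, and a bound from 0 counts is nearer to no difference there because fewer counts are left. Of 1289 list medians, 1181 lay inside, 101 outside, and 7 were sign changes of a list read as having a direction. Among the values counted as inside or outside, 93 had the other sign, all in lists not read as having a direction, and 14 of these were more than 1.5 times away. Of 240 cell shares, 69 lay outside, 56 of them at a minimum of 2 counts. No paired analysis was possible because the labels number no replicates and name no animals.

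The medians that answer the comparisons kept their sign in every setting. They were chosen as the answers after the data were seen, so this is no measure of how often lists keep their sign. The sign changes of lists with a direction, given below, are all in lists outside that choice. The oestrogen list ranged from 0.27 to 1.07 for pnd7 over pnd0, from 1.71 to 2.11 for pnd28 over pnd14, from 1.69 to 2.71 for pnd56 over pnd28 and from 4.72 to 6.51 for pnd56 over pnd0. The progesterone list ranged from 2.22 to 2.83 for pnd14 over pnd7. Cells thinned to equal depth moved the G2 and M phase median of pnd14 over pnd7 from −1.44 to −1.02, the MHC and interferon median of pnd28 over pnd14 from 1.22 to 0.78, and the oestrogen median of pnd56 over pnd28 from 2.23 to 2.71. A list minimum of 1 count moved S phase of pnd14 over pnd7 from −1.01 to −0.79 and the oestrogen median of pnd56 over pnd28 to 1.69. A minimum of 100 counts moved the oestrogen median of pnd56 over pnd0 from 5.57 to 6.51. Without run 1 the oestrogen median was 0.27 for pnd7 over pnd0 and 4.72 for pnd56 over pnd0. Without run 3 the G2 and M phase median was −1.03, and without run 7 the MHC and interferon median of pnd28 over pnd14 was 1.71. The cause of these shifts was not tested.

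Among lists read as having a direction, the sign changed at equal depth for the MHC and interferon list of pnd14 over pnd7 (−0.00569) and the steroid receptors of pnd28 over pnd14 (−0.0117). It changed at a minimum of 100 counts for the MHC and interferon list of pnd14 over pnd7 (−0.22). With a minimum of 1 count it changed for the progesterone list of pnd28 over pnd14 (0.0046) and the retinoid list of pnd56 over pnd28 (0.16). For these the cause was not tested. It changed for the stroma list of pnd28 over pnd14 without the smooth muscle-like cells (−0.00946), which hold 222 of the 324 stroma counts of pnd14 and 161 of the 328 of pnd28. It also changed for the stroma list of pnd56 over pnd28 without each gene's largest cell (−1.87), since 1 cell holds most of the Col3a1, Vim and Dcn counts. Among the lists without a direction, the oestrogen list of pnd14 over pnd7 went from −0.55 to 0.60 at a minimum of 100 counts. The Wnt list went to 0.16 and 0.12 at a minimum of 1 count for pnd14 over pnd7 and pnd28 over pnd14, and the patterning factors of pnd56 over pnd0 to 1.10. At equal depth the secretory list of pnd7 over pnd0 went to 0.37, endothelium of pnd28 over pnd14 to 0.04, and progenitor candidates, imprinted genes, S phase and G2 and M phase of pnd56 over pnd0 to 0.95, 0.13, 0.17 and 0.19.

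At a minimum of 2 counts per cell, Ltf was present in 33.3% of thinned pnd28 cells, against 57.6%, and Calb1 in 6.20% of thinned pnd14 cells, against 15.9%, as fewer cells can reach a higher count. The number of clusters ranged from 7 to 14. Agreement with the main clusters, as the adjusted Rand index (1 if identical), ranged from 0.433 with 1000 variable genes to 0.858 without cell cycle genes. The smooth muscle-like cells stayed together at Leiden resolution 0.5 but were merged with other cells, so that their cluster held 67.0% of pnd14 cells. With 1000 variable genes it held 8.09%, against 13.3%. A total without ribosomal and mitochondrial genes was not run, as the table holds no such rows, and pseudocounts were not run, as the values are counts. Depth limits the later ages most: pnd28 and pnd56 have 96248 and 81894 counts, so a gene without a count at pnd56 may still stand at the level that the floor of 3 counts allows, and the bound for Phax in pnd28 over pnd14 was −1.64 at equal depth against −2.47.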

Other observations

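All tests in this part were chosen after the results were seen, so an explanation that meets its test remains a hypothesis. Age as the cause could not be tested for any of the patterns, since 0 runs hold pnd28 cells together with cells of another age, and an age and its runs cannot be told apart.

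Prss29 and Prss28 were counted in 92.9% and 62.5% of pnd28 cells, the smooth muscle-like ones included. Counts per cell of Prss29 in the smooth muscle-like cells were 0.872 [0.608, 1.22] times those in the other pnd28 cells without the largest, while for Krt18 that ratio was 0.0811 [0.0166, 0.239]. Prss28 over Prss29 was 0.342 [0.167, 0.657] in the smooth muscle-like and 0.358 [0.296, 0.431] in the other cells. In the cell with the most of both it was 0.579 [0.510, 0.657], above the interval of the other cells, so their counts do not have the composition of that cell. The Prss29 and Krt18 ratios met the test for RNA outside the cells that reached every well. For such RNA, glandular secretion or broken gland cells are a candidate source, which was not tested. Reads moving between wells alike for every gene are argued against, because Astx4b, among 34 genes with at least 30 counts in 1 pnd28 cell, had none in the other cells, an upper bound of 0.102 of its largest cell against a share of 0.708 for Prss29. Why Prss28 and Prss29 differ in this from other secreted products, such as Wfdc2 with 2037 CPM in the smooth muscle-like and 9747 CPM in the other cells, stays open.

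For Ovgp1, the lowest pnd14 run lay 19.9 [12.2, 34.3] times above the highest pnd7 run. The naming rule had required every pnd14 run to lie above every pnd7 run. The direction was thus fixed by that choice and is no test of whether 1 run made the difference, while the size was not fixed. RNA outside the cells is argued against, because the level in the smooth muscle-like pnd14 cells was 0.0270 [0.00555, 0.0791] of that in the other cells. Clusters 2 and 3 were chosen as the pair with the most Ovgp1 at pnd14, so their higher Ovgp1 level follows from that choice. Cluster 3, with 27 of the pnd14 cells, was led by Ugt1a rows that share reads and entered the clustering as separate rows. Their 42 pnd14 cells held 8711 CPM of Ovgp1, with a median of 1 count per cell. The 93 cells of the largest pnd14 cluster held 375 CPM. The ciliated epithelium list was 20.1 [8.63, 57.4] times higher in the 42 cells than in that cluster, or 15 times without the cell with the most ciliated counts. Wt1 was at 607 against 51.3 CPM and Ltf at 1409 against 113, while Pax2 was at 146 against 400 and Acot7 at 474 against 3377. A candidate explanation is that some pnd14 cells came from a ciliated, Ovgp1-expressing epithelium such as that of the oviduct, which the CD326 sort would not remove. It rests on 51 ciliated counts in 11 of the 42 cells, and the labels give uterus as the only tissue. These cells held 18 of 39 pnd14 counts of Ccno, 15 of 18 of Ccdc153 and 8 of 9 of Mcidas. They held 5 of 8 of Dynlrb2, 4 of 4 of Tppp3, 1 of 1 of Ccdc113 and 0 of 6 of Tekt2. Tekt1 and Fam183b had no pnd14 count. The Tekt2 counts and part of the Ccno counts lay in other clusters, outside the contrast with the largest cluster, so ciliated counts did not all follow Ovgp1.

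Dcn, a proteoglycan gene of fibroblasts, was counted in most pnd28 cells. RNA with the composition of the 5 smooth muscle-like cells of the same run is argued against. Col1a2 plus Col3a1 over Dcn was 0.0885 [0.0413, 0.169] in the other pnd28 cells and 0.769 [0.54, 1.09] in those 5 cells. No cluster was named after stroma or fibroblasts, so RNA of stromal cells with another ratio was not tested. A single cell does not account for it either, as the level without the largest was 752.5 [578, 963] CPM, in 27 of 50 cells, against 54.7 [31.9, 87.6] CPM in the corresponding pnd14 cells. The age of the animals, run 9 and RNA of stromal cells with another ratio remain as open explanations.

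A set of 9 pnd0 cells, 5.20% of that age and from both of its runs, formed a cluster led by Upk3a, a urothelial surface protein gene, with H19, Adh1 and Krt7. Upk3a had 58 and 193 counts in runs 1 and 2 and none in any later run. Without run 2, which holds the higher H19 level, the bound for H19 in pnd56 over pnd0 was −2.59. No explanation for this group of cells was tested.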
